A study of Mus musculus with 42 samples.

How the data were processed

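Whole lung homogenates of 42 newborn mice were hybridised one mouse per array to Affymetrix 3' expression arrays, in 14 groups of 3. Per the labels' extract protocol each array holds the RNA of a separate mouse, so the replicates are animals. The deposited table gives 1 value per probe set and array on the log2 scale. The submitters' processing notes name GCOS and RMA, whose versions are not given in the sources used here. RMA, as the authors applied it, subtracts background, brings all arrays to one distribution of values and summarises the probes of a probe set. The deposited log2 values were used as they stand, with no further normalisation. The array's annotation version and the dates of hybridisation are not given in the sources used here.

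The table holds 45101 probe sets. The probe annotation used here lists genes for 35890 of them, of which 34958 carry exactly 1 symbol and 932 several, and 9211 have no listed gene. Probe sets with no symbol or several symbols were not tested. Symbols were compared with those of the mouse assembly GRCm38.p6 through their Entrez numbers for 34754 probe sets, and 0 changed. That assembly served only for symbols and for the order of genes along chromosomes. Where a gene had several probe sets, which held for 9012 genes, the one with the highest mean over the 42 arrays stood for it, which left 18194 genes.

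Groups came from the sample titles. All 42 arrays were fitted together with 14 group means in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with tables handled in the data.table package, version 1.17.8. The fit has 28 residual degrees of freedom, or 31.4 after moderation. There were 24 contrasts. Of these, 5 lead the account (P4 against P1 in wild type, knockout against wild type in air, 3 days of hyperoxia against air in wild type, knockout against wild type in hyperoxia, and the difference between genotypes in the hyperoxia effect). In each contrast p-values were adjusted by Benjamini-Hochberg over all genes, two-sided, and a gene was called at an adjusted p under 0.05. Mean contrasts average 4 ages in air (12 arrays against 12) or 3 in hyperoxia (9 against 9). Changes are given on the log2 scale with their standard error (SE) from the fit, and group values as mean ± standard deviation (SD, n = 3). For arrays, their number limits the precision.

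Gene lists for pathways, lung cell types and tissues that a lung sample can carry along were written from general knowledge. There were 34 lists with 595 genes, 556 of them measured. Each was tested with camera, which compares the mean test statistic of a list's genes with that of all other genes. It was run with its preset correlation of 0.01, and again with a correlation estimated per list. A list said to rank higher or lower did so by that mean. Adjustment ran over the 34 lists within a contrast. Beside the members called over all genes stands the number called when p was adjusted over the list alone. A list score is the mean deviation of its members from their means over the 42 arrays. For other tissues the score is given relative to its median over the 42 arrays. The groups, the tests, the lists, the choice of probe set, the named genes and most alternatives were fixed before the data were examined.

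Genes are named by rule. In each of the 5 leading comparisons these are the 6 largest rises and the 6 largest falls among called genes whose sign was the same at every age (mean contrasts) or whose replicates did not overlap between the groups (single ages). Predicted genes without a proper name and the sex genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were left out of that choice. For the 6 lists with the smallest camera p past the threshold, the 3 members with the smallest p in the list's direction were added. Nfe2l2, Nqo1, Gclc, Gclm, Hmox1, Cdkn1a, Mki67, Sftpc and Eln were reported whatever their values. In the other comparisons only genes already named were given.

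The procedure was tested on simulated data with the same group sizes. Genes changed by 0.5, 1 or 2 log2 units were recovered in 70.1%, 95.5% and 98.5% of cases for 3 days of hyperoxia in wild type, in 74.6%, 92.5% and 100% for P4 against P1, and in 79.1%, 98.5% and 100% for the mean difference between genotypes in the hyperoxia effect, with 9, 11 and 5 false calls among 18194 genes. In simulated data camera found 1 of 1 shifted lists and 0 of the others. Simulated genes varied independently of one another. Neither simulation therefore covers lists whose genes move together, or structure shared by arrays.

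The alternatives were cyclic loess normalisation, an intensity trend with robust variances, array weights, only the upper 60 percent of genes by mean level, the mean of all probe sets of a gene, every probe set on its own, a fit on only the arrays of the contrast, the replicate number as a block, a score of the sex genes as covariate, and leaving out each array in turn. Ddx3y is among the genes not named on the array, so 3 Y-linked genes entered that score. After the data were seen 2 more were added: scores of 5 other tissues (liver, heart muscle, skeletal muscle, fat and thymocytes) as covariates, and leaving aside the 9 arrays with one of those scores more than 4 log2 units above the median of all arrays. The thymocyte list of 12 genes was also written then. Other splits of the arrays into groups of the same sizes were counted, all 10 for 3 against 3 and 100 drawn where there are more. No sample and no column of values was left out.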

Results

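Gene expression was measured in the lungs of newborn mice that carried or lacked the gene Nfe2l2, which encodes NRF2, a transcription factor that switches on antioxidant and detoxifying enzymes. The 42 arrays fall into 14 groups of 3 pups. Wild-type (WT) and knockout (KO) pups in room air were sampled at P1, the day of birth, and at P2, P3 and P4. Pups of both genotypes were also sampled at P2, P3 and P4 after 1, 2 or 3 days in a chamber with 95% oxygen or more (hyperoxia), which began at P1, given as 24 h after birth, and ran 23 h a day in the company of foster dams. By the stated ages P1 is day 0 and P2 follows 1 day of exposure, so that start is read here as within the first 24 h. Each array gave log2 values for 18194 genes with a symbol, with array medians of 6.31 to 6.40. Arrays of one group correlated across genes with r from 0.972 to 0.997 (genes are not independent replicates), and 34 of 42 arrays resembled an array of their own group most.

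Nfe2l2 transcript was present in every WT array and near the bottom of the scale in every KO array. The probe set used for the gene read 10.86 ± 0.28 (SD, n = 21) in WT and 4.68 ± 0.29 (SD, n = 21) in KO, with ranges of 10.3 to 11.6 and 4.26 to 5.46. At single ages KO lay below WT by −5.75 to −6.38 log2 units, which are minimums, since the KO level lies near the arrays' 10th percentile (median 4.27). WT in air measured 10.51 ± 0.32, 10.95 ± 0.19, 10.67 ± 0.08 and 10.80 ± 0.04 from P1 to P4 (SD, n = 3), and WT in hyperoxia 10.85 ± 0.06, 10.96 ± 0.13 and 11.27 ± 0.28 after 1, 2 and 3 days. KO in air measured 4.76 ± 0.29, 4.59 ± 0.13, 4.35 ± 0.10 and 4.76 ± 0.11, and KO in hyperoxia 4.84 ± 0.21, 4.58 ± 0.23 and 4.89 ± 0.53. A second probe set read 6.49 ± 1.08 in WT and 6.53 ± 0.89 in KO (SD, n = 21), and checks nothing about the deletion.

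**Figure D1:**
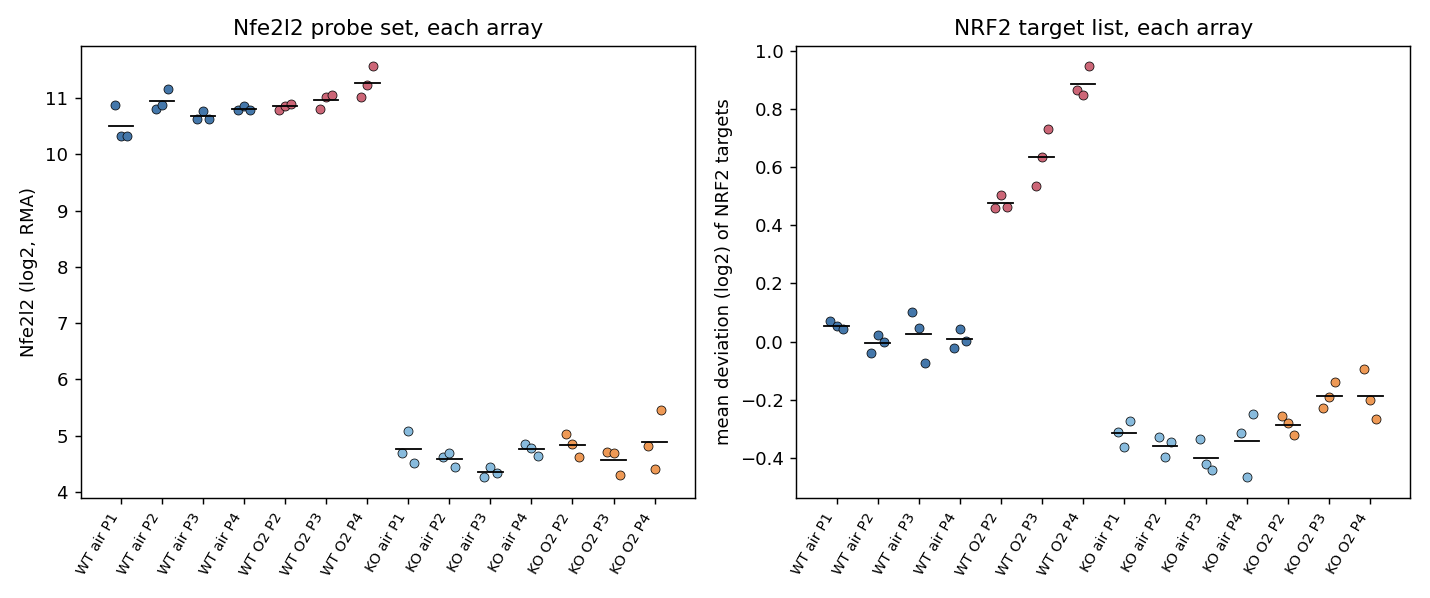
Log2 level of the Nfe2l2 probe set (left) and mean deviation of NRF2 targets from their means over all arrays, in log2 units (right), for each of the 42 arrays by group, with bars at the group means. WT arrays lie between 10.3 and 11.6 and KO arrays between 4.26 and 5.46, and the list mean reached 0.89 in WT after 3 days of hyperoxia.

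Transcripts of other organs were present in some of the lung arrays. The liver list averaged 2.55 log2 units above its median in WT air arrays, 1.53 in WT hyperoxia, 0.28 in KO air and −0.07 in KO hyperoxia, and reached 7.49 in WT air P2 replicate 2. Heart muscle genes passed 2 log2 units in 4 WT arrays and 0 KO arrays. Skeletal muscle genes passed it in 2 WT and 3 KO arrays, with 5.99 in KO air P3 replicate 2. Thymocyte genes passed it in 2 KO arrays, KO air P2 replicate 1 at 4.37 and replicate 3 at 3.48, and fat genes in 0 arrays, with at most 1.38.

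**Figure D2:**
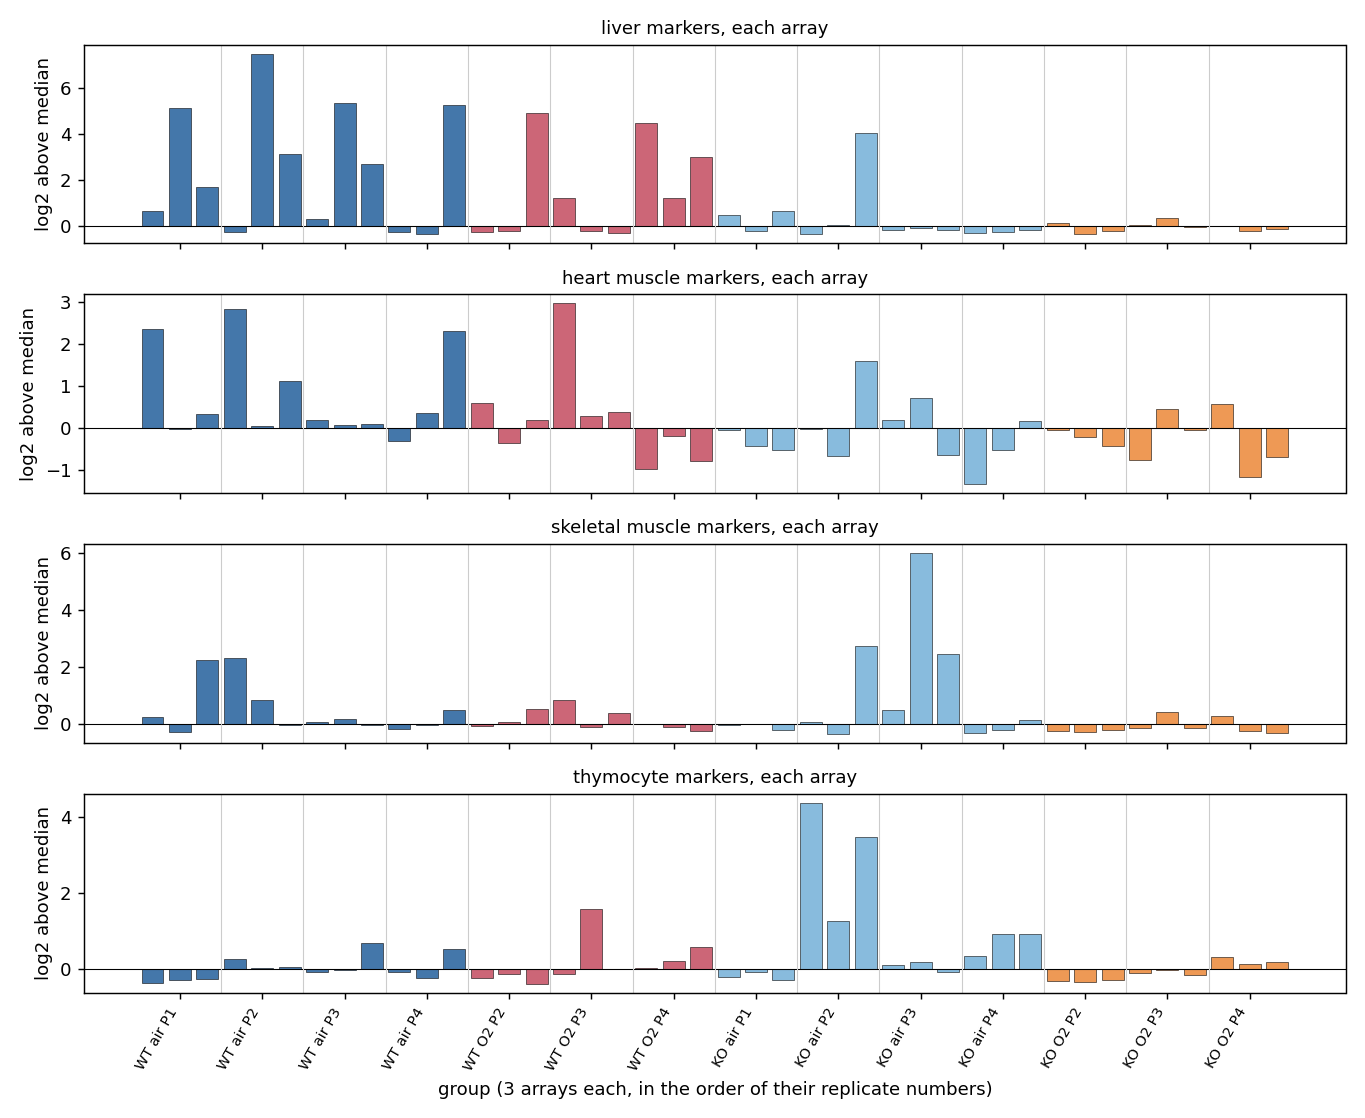
Scores of liver, heart muscle, skeletal muscle and thymocyte genes, each relative to the median of that score over all arrays (log2 units), 1 bar per array, grouped by genotype, exposure and age. Liver genes reached 7.49 in a WT array and thymocyte genes 4.37 in a KO array.

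The first comparison asks how gene expression in WT lung changes over the first days after birth in air. Between P1 and P4 the machinery of cell division rose. Melk, a kinase of dividing cells, went from 5.85 ± 0.29 to 9.06 ± 0.17 (SD, n = 3), a rise of 3.21 ± 0.29 (SE; 9.23-fold; limma adjusted p = 3.44e-09). Depdc1a rose by 3.51 ± 0.35 (11.4-fold; limma adjusted p = 1.83e-08), Aurkb, the mitotic kinase Aurora B, by 3.29 ± 0.33, and Cep55 and Bub1, the last a spindle checkpoint kinase, by 3.28 and 3.07. Pbk rose 9.83-fold. Mki67, the gene of the proliferation marker Ki-67, rose by 2.25 ± 0.28. In the opposite direction Inmt, a methyltransferase abundant in lung, fell from 12.32 ± 0.29 to 9.70 ± 0.12.

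Of the 24 mitosis genes 24 were higher at P4 and 24 when adjusted over the list alone, among them Ttk (2.79) and Prc1 (2.61). The list passed camera with adjusted p = 2.81e-31, and gave adjusted p = 0.121 with an estimated correlation. Of 25 DNA replication genes 24 were higher, also 24 adjusted over the list alone, among them Ccne2, a cyclin of the start of replication (2.57), Dtl (2.22) and Gins2 (1.41). This list had camera adjusted p = 4.32e-25, and adjusted p = 0.123 with an estimated correlation. Of the 15 markers of alveolar type 2 cells, the surfactant producers, 13 were lower by either count, with surfactant protein D (Sftpd) at −1.20 ± 0.11 (SE), the transcription factor Cebpa at −0.88 and the protease Ctsh at −0.89. The camera adjusted p was 2.65e-09, and adjusted p = 0.240 with an estimated correlation. Surfactant protein C (Sftpc) was an exception at −0.06 ± 0.05 (SE; limma adjusted p = 0.413). Of 15 alveolar type 1 markers 11 were lower, and 12 lower and 1 higher when adjusted over the list alone, among them Lmo7 (−1.01), Krt7 (−0.94) and Hopx (−0.59). The list had camera adjusted p = 1.43e-07, and adjusted p = 0.240 with an estimated correlation.

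Other cell type lists moved over the same days. Of 15 myofibroblast and smooth muscle markers 6 were higher, 8 adjusted over the list alone, of 20 matrix genes 11 were higher and 2 lower, 15 and 3 adjusted over the list alone, and of 16 neutrophil markers 7 were lower, 8 adjusted over the list alone. Their camera adjusted p was 9.19e-04, 1.01e-04 and 5.09e-05, and adjusted p = 0.381, 0.496 and 0.242 with an estimated correlation.

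Circadian clock genes were lower at P4 than at P1: 10 of 16 were lower, and 10 lower and 1 higher when adjusted over the list alone. The camera adjusted p was 7.77e-07, and still adjusted p = 0.0155 with an estimated correlation. The lower genes include Per1 (−1.74 ± 0.28, SE), Cry2 (−0.96) and Tef (−0.76). The hour at which pups were taken is not given, so age and hour of day cannot be told apart for these genes. Of 14 genes that respond to glucocorticoids 8 were lower, and 9 adjusted over the list alone, with Klf9 at −1.86 and Errfi1 at −1.50 beside Per1, which both lists hold. The camera adjusted p was 3.87e-06, and adjusted p = 0.240 with an estimated correlation. Klf15 (−2.07), the matrix protein gene Smoc2 (−2.09) and Olfm4 (−2.03) were also among the largest falls. The cell cycle inhibitor Cdkn1a fell by 1.10 on the log2 scale, while elastin (Eln) at −0.32 ± 0.13 (limma adjusted p = 0.0907, called in 3 of 17 alternatives) and Nqo1, Gclc, Gclm, Hmox1 and Nfe2l2 were not called. These last 5 read −0.12, −0.03, −0.04, −0.07 and 0.30 in that order, but the second Nfe2l2 probe set fell from 8.64 ± 0.60 to 5.43 ± 0.36 (SD, n = 3), by −3.21 (limma adjusted p = 1.20e-10), and the mean of both was at −1.46 (limma adjusted p = 4.04e-09). Nfe2l2 was called in 3 of 17 alternatives, these 2 and array weights (0.43). The second probe set read alike in WT and KO arrays (6.49 and 6.53), so it does not follow the deletion. The 2 calls that use it therefore cannot be read as a fall of the deleted transcript. The heart genes Myl2 and Myh7 were lower by −5.06 ± 1.18 and −2.07 ± 0.44 (SE). At P1 Myl2 ran from 8.39 to 14.17 between the 3 arrays, of which replicate 1 held the most heart transcripts. By limma 4083 genes were called, 2034 higher and 2049 lower, and 480 of them changed at least 2-fold. Array weights called 6381 genes. The Myh7 call ended (limma adjusted p = 0.0763) in a fit on the arrays of this contrast alone, the highest of its 16 alternatives, which start at 6.31e-05.

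At P2 and P3 the same comparison with P1 called 2638 genes (1137 higher) and 3749 genes (2035 higher). Melk was up by 1.94 and Mki67 by 1.49 at P2, and Per1 was down at −2.49. At P2 43.1% of called genes were higher, against 57.4% after loess. A fit on only the arrays of the contrast called 860 genes at P2, and array weights called 6254 at P3.

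Whether the change from P1 to P4 is the same in the knockout lung was asked next. This compares end points only, and the change to P2 or P3 was not tested between genotypes. At P3 the course did differ, with mean mitosis scores of 0.63 in WT and −0.17 in KO and 3939 genes called by genotype. From P1 to P4 in air, KO pups also showed a rise in cell division genes, with Melk up by 3.03, Aurkb by 3.11 and Mki67 by 2.81. Inmt was lower by −3.14 ± 0.27 (SE) and Sftpd by −0.93. All of the 24 mitosis genes were higher (camera adjusted p = 5.96e-44, and adjusted p = 0.0616 with an estimated correlation), and 12 of 15 type 2 markers were lower, 13 adjusted over the list alone (camera adjusted p = 1.18e-07, and adjusted p = 0.501 with an estimated correlation). In KO 3932 genes were called, and 1101 higher and 1277 lower genes were shared with WT, where 164 and 277 would be shared by independent sets. A direct limma test of the difference between genotypes called 5 genes (1926 at an unadjusted p under 0.05), which are named here after their values were seen: Hdhd3 (−0.95), Dnm1 (−0.64), Calr (−0.43), Rbm33 (0.73) and Srp54b (0.70). In that test 5 lists passed camera, all with 0 genes called. Mitosis genes ranked higher in KO, with a mean of 0.24 (camera adjusted p = 0.00405), which turned to −0.0051 with scores of other tissues as covariates. Neutrophil markers, glucocorticoid response and interferon response (camera adjusted p = 0.00209, 0.00405 and 0.00907) also ranked higher, and these 4 lists gave adjusted p = 0.863 with an estimated correlation. Of the 5 the circadian clock list held with an estimated correlation: 0 of 16 genes were called, 4 were higher when adjusted over the list alone, and camera gave adjusted p = 4.13e-08, then adjusted p = 0.00321. The count of 5 genes moved with every array left out: to 42, 1 and 1 without WT P1 replicates 1, 2 and 3, to 2, 1 and 1 without WT P4 replicates 1, 2 and 3, to 1, 3 and 8 without KO P1 replicates 1, 2 and 3, and to 2, 2 and 1 without KO P4 replicates 1, 2 and 3.

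The next comparison asks what the loss of Nfe2l2 changes in lungs in air. Averaged over P1 to P4, glutathione transferase Gsta3, an NRF2 target, was lower in KO by −2.38 ± 0.14 (SE; 5.22-fold; limma adjusted p = 5.73e-14). At single ages it ran from −2.27 to −2.56. The aldehyde oxidase Aox1 was at −1.26 ± 0.09 and the glutathione peroxidase Gpx2 at −1.06 ± 0.08 (SE). Nqo1, a quinone reductase, fell by 0.43 on the log2 scale, Gclc, which makes the first step of glutathione synthesis, fell by 0.44 and heme oxygenase (Hmox1) by 0.33. The partner subunit Gclm was not called at −0.01 ± 0.06 (limma adjusted p = 0.925).

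Of 31 measured NRF2 targets 22 were lower in KO, 22 adjusted over the list alone, and 9 did not pass. Camera gave adjusted p = 3.40e-16, which held as adjusted p = 0.00413 with an estimated correlation. Macrophage genes were lower for 8 of 18 markers, and 12 adjusted over the list alone, among them the scavenger receptor Marco (−0.83 ± 0.16, SE), Siglecf (−0.59) and the growth factor receptor Csf1r (−0.39). Their camera adjusted p was 9.94e-05, and adjusted p = 0.521 with an estimated correlation. Of 18 respiratory chain genes 7 were lower, 8 adjusted over the list alone, by small steps such as Uqcrc2 (−0.30), Ndufa4 (−0.26) and Ndufb5 (−0.21), the last not called by the mean of its probe sets (limma adjusted p = 0.0664). The camera adjusted p was 0.00174, and adjusted p = 0.782 with an estimated correlation. Over its alternatives the list mean ran from −0.28 to −0.09. The air arrays highest in this list were those highest in heart genes: WT P1 replicate 1, P2 replicate 1 and P4 replicate 3, at 0.34, 0.41 and 0.28. Mki67 fell by 0.59 on the log2 scale, and Cdkn1a (0.10) and Sftpc (0.01) were not called. Another Sftpc probe set was at 0.32 (limma adjusted p = 0.0103), and the mean of the probe sets at 0.16 (limma adjusted p = 0.00742). Eln (0.18 ± 0.07; 0.43 by the mean of its probe sets, 0.68 in one of them and 0.42 with scores of other tissues as covariates) was called with limma adjusted p = 0.0448, which ended (0.0529 to 0.103) without any one of WT P1 replicates 1 and 3, P2 replicate 2, P3 replicates 2 and 3, P4 replicates 1 and 2, KO P1 replicates 1, 2 and 3, P2 replicates 2 and 3, P3 replicates 1 and 3, and P4 replicates 1 and 3.

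Other genes were higher in KO. The tripartite motif gene Trim12c stood at 4.06 to 4.34 in WT groups and 7.74 to 8.45 in KO groups, a difference of 3.83 ± 0.11 (SE; limma adjusted p = 1.29e-22). The WT level lies near the arrays' 10th percentile as well, so the difference is a minimum and no fold is given. Rbm45 (1.87), Trim68 (1.61), Veph1 (1.35) and Npl (1.35) were also higher. Trim12c and Trim68 lie near one another on chromosome 7, and Rbm45 lies on chromosome 2 near Nfe2l2. Among genes of antigen presentation the class I molecules H2-K1 (1.14 ± 0.06) and H2-D1 (1.09 ± 0.06) rose, with H2-DMa at 0.28 and H2-Q2, of the same family, at 1.35. In that list 6 of 13 were higher and 1 lower, 7 and 1 adjusted over the list alone, with camera adjusted p = 0.00174 and adjusted p = 0.782 with an estimated correlation. Thymocyte genes moved beside them, at a mean of 0.92 in KO air and 0.03 in WT air. Without the arrays high in other tissues the list had camera adjusted p = 0.148. With scores of other tissues as covariates its mean turned from higher to −0.0094, H2-Q2 dropped to 0.58 and H2-DMa to 0.02, both no longer called (limma adjusted p = 0.112 and 0.859, the highest of 34 and 35 alternatives).

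Liver genes were lower in KO air lungs: 9 of 10, and 10 adjusted over the list alone, with camera adjusted p = 0.00174 and adjusted p = 0.782 with an estimated correlation. They differed by much with wide errors, as in alpha-fetoprotein (Afp, −3.89 ± 1.20), albumin (Alb, −3.06 ± 1.01), fibrinogen (Fga, −2.90 ± 0.94), Igfbp1 (−2.85 ± 0.86) and Ahsg (−2.50 ± 0.86, SE), because single WT arrays held much of them. Afp and Igfbp1 were called in 34 of 34 alternatives, but ran from −4.65 to −2.07 and from −3.43 to −0.46. Heart genes were lower for 6 of 14, and 8 adjusted over the list alone, such as Pln (−1.19), Myl3 (−1.01) and Myh6 (−0.98), with camera adjusted p = 0.00294 and adjusted p = 0.782 with an estimated correlation. Without the arrays high in other tissues Alb was at −1.73 and Ahsg at −1.05, no longer called (limma adjusted p = 0.0686 and 0.102). Calls of Alb, Fga and Ahsg ended in a fit on the air arrays alone (limma adjusted p = 0.0532, 0.0528 and 0.0698). Without WT P3 replicate 2 they had adjusted p = 0.0519, 0.0507 and 0.0677 (limma), and without WT P4 replicate 3 adjusted p = 0.0547, 0.0501 and 0.0682. Without WT P1 replicate 2 Alb (0.0505) and Ahsg (0.0646) ended, as did Ahsg without WT P2 replicate 2 (0.0673) and KO P2 replicate 1 (0.0510). Those of Myh6 and Pln ended without WT P1 replicate 1 (limma adjusted p = 0.0620 and 0.0669), WT P2 replicate 1 (0.0609 and 0.0656), WT P4 replicate 3 (0.0656 and 0.0634), KO P2 replicate 2 (0.0549 and 0.0514) and KO P3 replicate 3 (0.0565 and 0.0536), and that of Myh6 also without KO P4 replicate 1 (0.0597). With array weights both ended too (limma adjusted p = 0.0603 and 0.0641), as did Myh6 with the mean of its probe sets (0.0707) and Pln in a fit on the air arrays alone (0.0612).

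In all 5271 genes were called by limma for the mean of the 4 ages, 2646 higher and 2625 lower in KO, and 85 of them differed at least 2-fold. With scores of other tissues as covariates 2884 were called. At single ages the counts were 1233 at P1 (777 higher), 2391 at P2 (1451 higher), 3939 at P3 (1636 higher) and 132 at P4 (54 higher). After loess 46.8% of the genes at P2 were higher, against 60.7%, and 55.4% at P4, against 40.9%. In all 4 ages 32 genes were higher and 29 lower. NRF2 targets were lower at each age: 10 of 31 at P1, 15 at P2 (with 1 higher), 18 at P3 and 6 at P4, with camera adjusted p of 9.18e-13, 3.20e-08, 2.67e-09 and 1.16e-14. Those gave adjusted p = 0.00800, 0.141, 0.0840 and 0.00744 with an estimated correlation. At P2 lymphocyte markers were higher in KO (11 of 16, camera adjusted p = 1.91e-07, and adjusted p = 0.296 with an estimated correlation), with the recombinase gene Rag1 at 12.64, 8.97 and 12.05 in the 3 KO arrays and 6.78 ± 0.34 (SD, n = 3) in WT. At P3 cell division lagged in KO, with Melk at −1.31 and Mki67 at −1.21. There 20 of 25 DNA replication genes were lower, 23 adjusted over the list alone (camera adjusted p = 1.05e-11, and adjusted p = 0.715 with an estimated correlation). Skeletal muscle transcripts were highest in that group of arrays.

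Single arrays moved the smaller of these counts. At P1 697, 684, 673 and 692 genes were called without WT replicate 2, WT replicate 3, KO replicate 1 and KO replicate 2, and 272 in a fit on those arrays alone. The count at P2 fell to 1210 without KO replicate 1, the array richest in thymocyte transcripts, and to 9 in a fit on those arrays alone. It was 173 with scores of other tissues as covariates and 472 without the arrays high in them. At P4 64, 66, 61 and 84 genes were called without WT replicates 1, 2 and 3 and without KO replicate 3.

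The third comparison asks what hyperoxia does to WT newborn lung. After 3 days the acute phase gene Saa3 was at 13.98 ± 0.34, against 8.17 ± 0.25 (SD, n = 3) in air, a rise of 5.81 ± 0.41 (SE; 56.2-fold; limma adjusted p = 8.98e-13). The cytokine gene Il6 rose by 5.64 ± 0.37 (SE), from 4.34 ± 0.01 to 9.98 ± 0.89 (SD, n = 3), at the least, since its air level lies near the arrays' 10th percentile. The monocyte attractant Ccl2 rose by 4.56 ± 0.27, Ptgs2, which makes prostaglandins, by 4.52 ± 0.40, Ereg, a growth factor, by 4.29 ± 0.25 and Eda2r, a receptor controlled by p53, by 4.37 ± 0.26 (SE). The p53 target Cdkn1a, which stops the cell cycle, rose by 3.19 ± 0.16 (9.10-fold; limma adjusted p = 1.78e-15).

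Of 21 cytokine and acute inflammation genes 19 were higher by either count, among them Socs3 (2.92), with camera adjusted p = 2.77e-26, and adjusted p = 6.68e-04 with an estimated correlation. Markers of inflammatory cells ranked higher beside them, with 7 of 16 neutrophil markers higher by either count and 11 of 18 macrophage markers higher and 1 lower, 11 and 2 adjusted over the list alone. Their camera adjusted p was 0.00251 and 0.00134, and adjusted p = 0.440 and 0.316 with an estimated correlation. Of 22 p53 targets 19 were higher, 19 higher and 1 lower adjusted over the list alone, with Aen at 2.24 and Phlda3 at 2.02. With camera the adjusted p was 1.47e-25, and adjusted p = 5.79e-04 with an estimated correlation. Of 31 NRF2 targets 23 were higher and 1 lower, 23 and 2 adjusted over the list alone (camera adjusted p = 2.52e-17, and adjusted p = 0.00108 with an estimated correlation). Gpx2 rose by 2.79 ± 0.16 (6.94-fold), Gclc by 2.32 ± 0.14, the epoxide hydrolase Ephx1 by 2.00 ± 0.11, Hmox1 by 1.88 ± 0.13, Nqo1 by 0.88 ± 0.16 and Gclm by 0.77 ± 0.12 (SE). Nfe2l2 itself was at 0.46 ± 0.18 (SE; limma adjusted p = 0.0532), and was called under several alternatives, such as without WT hyperoxia P4 replicate 1 (0.59, limma adjusted p = 0.0299) and with the mean of its probe sets (1.08). That mean includes the second probe set, which does not follow the deletion. The 17 alternatives for Nfe2l2 run from 1.03e-07 to 0.279.

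Genes of cell division were lower after 3 days. In DNA replication 18 of 25 were lower, 21 adjusted over the list alone, as were Mcm4 (−0.79), Mcm6 (−0.78), parts of the replicative helicase, and Gins2 (−0.67). They had camera adjusted p = 7.59e-07, and adjusted p = 0.456 with an estimated correlation. Of 24 mitosis genes 17 were lower, 21 adjusted over the list alone, with Kif20a at −1.31, Cenpf at −1.24 and Mki67 at −1.10 ± 0.28 (SE). Their camera adjusted p was 5.60e-06, and adjusted p = 0.456 with an estimated correlation. Of 14 genes of the TGF-beta response 9 were higher by both counts, among them Thbs1 (2.18), Bhlhe40 (2.17) and Ccn1 (1.69), with camera adjusted p = 1.81e-05 and adjusted p = 0.176 with an estimated correlation. The largest falls were in Scgb3a1, a secretory protein of the airways (−3.83 ± 1.22), Chad (−2.50), Lypd2 (−2.50), Slitrk6 (−2.40 ± 0.23), Cckar (−2.36) and Tnni1, a slow muscle troponin (−2.31 ± 0.79, SE). Sftpc (−0.01) and Eln (−0.09) were not called. Heart muscle genes ranked lower beside Tnni1, with 2 of 14 called and 1 adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.669 with an estimated correlation), which ended without WT air P4 replicate 3 (camera adjusted p = 0.202). Of the 15 alternatives for this list 11 passed.

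By limma 5010 genes were called after 3 days, 2732 higher and 2278 lower, and 568 changed at least 2-fold. The call of Scgb3a1, whose 17 alternatives run from adjusted p = 0.00532 to 0.128, ended with tissue scores as covariates, without the arrays high in them, and without WT air P4 replicate 1 or WT hyperoxia P4 replicates 1 and 3 (limma adjusted p = 0.0617, 0.128, 0.0567, 0.118 and 0.0598). That of Tnni1, with 17 alternatives from 0.00186 to 0.262, ended without the arrays high in other tissues, and without WT air P4 replicate 3 or WT hyperoxia P4 replicates 1 and 3 (limma adjusted p = 0.262, 0.227, 0.0719 and 0.0799).

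The first 2 days showed which of these changes came early. After 1 day 788 genes were called (480 higher), with Gpx2 already up by 1.70 ± 0.15 (SE), Nqo1 by 1.05 and Cdkn1a by 1.41. NRF2 targets were higher for 18 of 31, and 21 adjusted over the list alone (camera adjusted p = 3.75e-21, and adjusted p = 7.19e-04 with an estimated correlation). Of 22 p53 targets 9 were higher and 1 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 4.19e-08, and adjusted p = 0.0856 with an estimated correlation). Of 21 cytokine genes 1 was higher, 3 adjusted over the list alone (camera adjusted p = 0.0380, and adjusted p = 0.632 with an estimated correlation). After 2 days 982 genes were called (525 higher), with 16 of 22 p53 targets higher, 18 adjusted over the list alone (camera adjusted p = 1.01e-42, and adjusted p = 8.45e-06 with an estimated correlation). Ccl2 was up by 2.37 and Il6 by 1.34 ± 0.37 (SE; limma adjusted p = 0.0295). DNA replication genes, lower after 3 days, ranked higher after 1 day, with 1 of 25 called and 4 adjusted over the list alone (camera adjusted p = 4.79e-05, and adjusted p = 0.632 with an estimated correlation). After loess 42.6% of the genes at 1 day were higher, against 60.9%. The 1-day count fell to 524, 367 and 231 without WT air P2 replicate 2 and WT hyperoxia P2 replicates 1 and 2. The 2-day count fell to 637, 458 and 498 without WT air P3 replicates 1, 2 and 3, and to 542 and 598 without WT hyperoxia P3 replicates 1 and 3. A fit on only the arrays of the contrast called 12 genes at 1 day and 483 at 2 days, and array weights called 1232 and 3739.

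The same exposure in KO asks which of these changes occur without NRF2. After 3 days Saa3 rose by 6.06 ± 0.41, Ccl2 by 4.47 ± 0.27, Il6 by 4.44 ± 0.37 and Cdkn1a by 3.18 ± 0.16 (SE). Of 22 p53 targets 20 were higher (camera adjusted p = 1.16e-20, and adjusted p = 0.00226 with an estimated correlation). Of 21 cytokine genes 19 were higher, 20 adjusted over the list alone (camera adjusted p = 1.71e-20, and adjusted p = 0.00348 with an estimated correlation), as were 7 of 16 neutrophil markers, 8 adjusted over the list alone, and 11 of 18 macrophage markers by either count (camera adjusted p = 0.00252 and 5.58e-04, and adjusted p = 0.396 and 0.374 with an estimated correlation). Of 24 mitosis genes 23 were lower, with Mki67 at −1.73 (camera adjusted p = 3.87e-12, and adjusted p = 0.374 with an estimated correlation). After 2 days 18 of 25 DNA replication genes were higher, 23 adjusted over the list alone (camera adjusted p = 1.31e-14, and adjusted p = 0.274 with an estimated correlation), against KO air P3 arrays in which they were lower than in WT. The NRF2 list was higher after 2 days, with 8 of 31 called and 10 adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.280 with an estimated correlation), and did not pass camera at 1 and 3 days. Gpx2 was at 0.01, 0.07 and 0.45 after 1, 2 and 3 days, the last called (limma adjusted p = 0.0269), and Nqo1 was lower after 3 days (−0.55; limma adjusted p = 0.00958). Hmox1 rose by 1.66 and Gclc by 1.00 after 3 days.

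In KO 1648, 2288 and 5760 genes were called after 1, 2 and 3 days (1043, 1614 and 3089 higher). After 3 days 1925 higher and 1515 lower genes were shared by the genotypes, against 464 and 334 for independent sets, and 11 and 7 went opposite ways. Y-linked transcripts were present in 3 of 3 KO hyperoxia P4 arrays and 0 of 3 KO air P4 arrays, so sex and exposure cannot be separated within those 6 arrays. With the sex-gene score as covariate over all arrays 5067 genes were called. After loess 49.0% and 59.8% of the called genes were higher at 1 and 2 days, against 63.3% and 70.5%. At 1 day Rag1 was lower by −6.52 ± 0.84 (SE), and the air arrays it is compared with hold the thymocyte transcripts. The 1-day count was 12 with scores of other tissues as covariates, 149 without the arrays high in them, and 4 in a fit on only its arrays. Without KO air P2 replicates 1, 2 and 3 it was 707, 3125 and 866, and without KO hyperoxia P2 replicates 1 and 2 it was 807 and 994. The 2-day count fell to 1356 without KO hyperoxia P3 replicate 3. Array weights called 3048 and 4391 genes at 1 and 2 days.

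**Figure D3:**
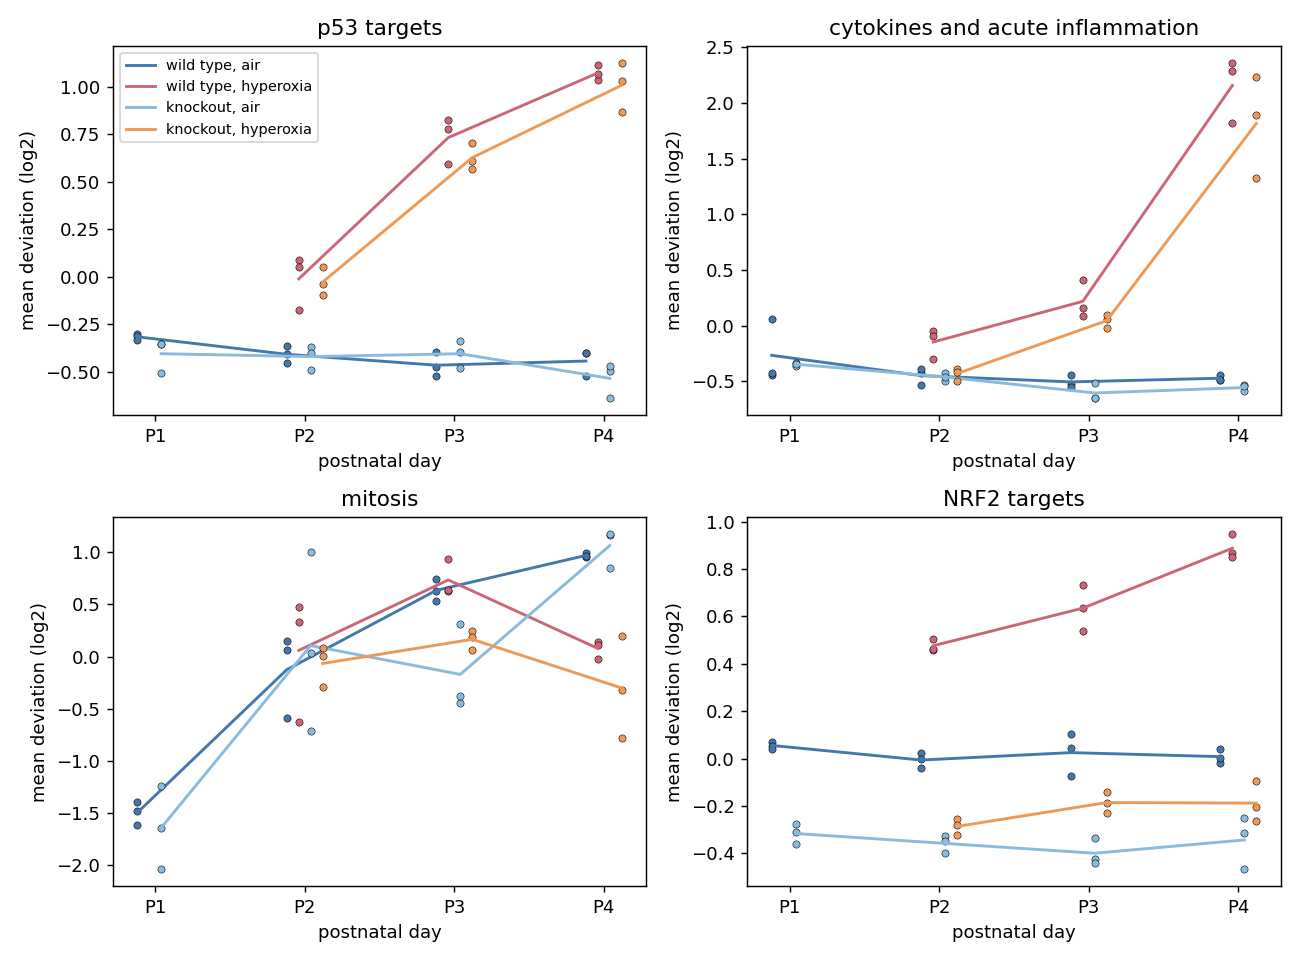
Mean deviation (log2 units) of p53 targets, cytokine and acute inflammation genes, mitosis genes and NRF2 targets from their means over all arrays, by age, genotype and exposure, with points for arrays and lines through group means. After 3 days the p53 list stood at 1.07 in WT and 1.01 in KO, and the NRF2 list at 0.89 in WT and −0.19 in KO.

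The next comparison asks how lungs without Nfe2l2 differ from WT under hyperoxia. Averaged over 1 to 3 days, Gpx2 was lower in KO by −3.16 ± 0.09 (SE; 8.94-fold; limma adjusted p = 7.29e-23), from 9.86 ± 0.15 in WT to 6.68 ± 0.32 (SD, n = 3) in KO after 3 days. Gsta3 was lower by −2.98 ± 0.17, Aox1 by −2.11 ± 0.10, Nqo1 by −1.56 ± 0.09 (2.94-fold), Gclc by −1.30 ± 0.08, Hmox1 by −0.76 ± 0.08 and Gclm by −0.50 ± 0.07 (SE). Thioredoxin reductase Txnrd1 (−1.25) and the glutathione transferase Gstm1 (−1.30) were lower as well.

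Of 31 NRF2 targets 28 were lower in KO, and 30 adjusted over the list alone. Camera gave adjusted p = 1.03e-66, which held as adjusted p = 2.47e-08 with an estimated correlation. It held after 1, 2 and 3 days as well, with 22, 26 and 27 genes lower (adjusted p = 8.08e-07, 1.45e-06 and 5.11e-07 with an estimated correlation). Endothelial markers were higher for 8 of 20, and 14 adjusted over the list alone, such as the vessel genes Tie1 (0.42), Pecam1 (0.36) and Tek (0.32), with camera adjusted p = 5.89e-06 and adjusted p = 0.732 with an estimated correlation. Every KO array had a higher endothelial score than every WT array after 1 day, and again after 2 days. After 3 days the scores were −0.38, −0.37 and −0.02 in KO and −0.23, −0.21 and −0.10 in WT, which is no rise. Macrophage markers were lower for 6 of 18, and 10 adjusted over the list alone, such as Marco (−1.03 ± 0.18), Csf1r (−0.47) and Adgre1 (−0.42), with camera adjusted p = 2.98e-05 and adjusted p = 0.231 with an estimated correlation. Of 12 club cell markers 4 were lower, among them Aldh1a1 (−1.84 ± 0.16, SE), Ces1d (−0.63) and Kcnk2 (−0.58), with camera adjusted p = 1.15e-04 and adjusted p = 0.461 with an estimated correlation. Of 23 lung development signals 7 were higher and 1 lower, 10 and 1 adjusted over the list alone, among them Wnt2 (0.78), Axin2 (0.47), a target of Wnt signalling, and Gli1 (0.47), of the hedgehog pathway. Camera gave adjusted p = 6.44e-04, and adjusted p = 0.0797 with an estimated correlation.

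Mitosis genes ranked lower (camera adjusted p = 1.91e-05, and adjusted p = 0.819 with an estimated correlation) with 2 of 24 called, Mki67 (−0.55 ± 0.16; limma adjusted p = 0.0249) and Foxm1 (−0.22; limma adjusted p = 0.0198), while Plk1 was at −0.47 (limma adjusted p = 0.0572) and was called in 9 of 29 alternatives (0.00164 to 0.149). The Mki67 call ended without WT P2 replicates 1 and 2, WT P3 replicate 2, KO P2 replicate 2 and KO P4 replicate 2 (limma adjusted p = 0.0507, 0.0513, 0.0552, 0.0524 and 0.0637), and that of Foxm1 without KO P4 replicate 1 (limma adjusted p = 0.0538) and with the mean of its probe sets (0.267). Trim12c (3.88), Rbm45 (2.31), Trim68 (1.67), the integrin Itga6 (1.47), Sirpb1a (1.23) and C1galt1 (1.06) were higher in KO. Itga6 lies near Nfe2l2 on its chromosome, as Rbm45 does. Trim34a (−2.09) and Lypd6 (−1.96) were among the largest falls, with another Trim34a probe set in the opposite direction at an unadjusted p under 0.05. Cdkn1a (−0.14), Sftpc (−0.03, with another probe set opposite) and Eln (0.19) were not called. Eln was called in 5 of 29 alternatives (limma adjusted p from 0.0011 to 0.255): with array weights (0.22), tissue scores as covariates (0.27), the mean of its probe sets (0.39), another probe set (0.59) and without WT P3 replicate 1 (0.24).

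Liver genes ranked lower in KO here too. Relative to the median of all arrays their score averaged 1.53 in WT and −0.07 in KO. In the list 0 of 10 genes were called (camera adjusted p = 0.0180, and adjusted p = 0.819 with an estimated correlation). Of its 27 alternatives 21 passed, and it ended without WT P2 replicate 3 (camera adjusted p = 0.167) and without WT P4 replicate 1 (0.0596).

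By limma 2270 genes were called, 1146 higher and 1124 lower, and 43 differed at least 2-fold. After loess 35.2% were higher, against 50.5%, and array weights and every probe set called 4530 and 4037. Of the genes called in air 769 higher and 761 lower ones were called in hyperoxia too, against 167 and 162 for independent sets, on separate arrays. At single ages 538, 934 and 1786 genes were called after 1, 2 and 3 days (375, 564 and 668 higher), and Il6 was lower after 3 days at −1.30 (limma adjusted p = 0.0242). After loess 49.4% and 37.9% were higher at 1 and 2 days, against 69.7% and 60.4%. Without WT P2 replicates 1 and 2 and KO P2 replicates 1, 2 and 3 the 1-day count was 186, 240, 236, 286 and 264. Without WT P3 replicates 1 and 3 and KO P3 replicates 1, 2 and 3 the 2-day count was 518, 598, 487, 612 and 357. Without WT P4 replicates 1 and 3 and KO P4 replicates 1 and 2 the 3-day count was 1144, 1041, 1163 and 932.

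The last comparison tests directly whether the hyperoxia effect differs between the genotypes. The clearest differences were in NRF2 targets, whose rise in WT was missing or smaller in KO. Gpx2 differed by −2.12 ± 0.13 (SE; limma adjusted p = 6.44e-13): WT went from 7.07 ± 0.08 in air at P4 to 9.86 ± 0.15 after 3 days, and KO was at 6.68 ± 0.32 (SD, n = 3). Srxn1, which restores peroxiredoxins, differed by −1.42 ± 0.13, Nqo1 by −1.22 ± 0.13, Txnrd1 by −0.81 ± 0.07, Gclc by −0.80 ± 0.11, Gclm by −0.54 ± 0.10 and Hmox1 by −0.42 ± 0.11 (SE). The last was called with limma adjusted p = 0.0470, and 14 of its 47 alternatives (0.00157 to 0.0840) made that call. Of 31 NRF2 targets 16 differed downward, and 21 adjusted over the list alone. Camera gave adjusted p = 3.66e-39, which held as adjusted p = 4.95e-06 with an estimated correlation.

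For p53 targets no such difference passed camera, and Cdkn1a was at −0.46 ± 0.13 (SE; limma adjusted p = 0.0740, called in 3 of 47 alternatives). Cytokine genes ranked lower (camera adjusted p = 0.0402, and adjusted p = 0.844 with an estimated correlation) with 0 of 21 called. That list passed in 29 of 46 alternatives, and among others not after loess (camera adjusted p = 0.0935) or in the upper 60 percent of genes (0.581), where its mean went from −0.20 to −0.05. Mki67 (0.00), Sftpc (−0.04), Eln (−0.02) and Nfe2l2 (−0.01) were not called. Hdc, which makes histamine, differed most upward, at 1.38 ± 0.15 (SE; limma adjusted p = 5.86e-07). At P3, where the difference was larger than this mean, it went from 10.37 ± 0.08 in air to 9.33 ± 0.24 in hyperoxia in WT, and from 8.35 ± 0.17 to 9.56 ± 0.22 (SD, n = 3) in KO. Slitrk6 (0.95), the alarmin Il33 (0.72), Ppp1r3c (0.70), the Wnt inhibitor Wif1 (0.68) and the clock gene Nr1d2 (0.65) also differed upward. Without the arrays high in other tissues they were at 0.77, 0.56, 0.53, 0.46 and 0.66, no longer called on fewer arrays (limma adjusted p = 0.0849, 0.132, 0.0957, 0.152 and 0.0911).

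T cell genes differed downward, beside the thymocyte transcripts of the KO air P2 arrays: Rag1 by −2.85 ± 0.69, Trbv1 by −2.52, Ccr9 by −2.29, Cd3g by −1.96, Thy1 by −1.74, Gzma by −1.67 and Cd3d by −1.58. Of 16 lymphocyte markers 4 were called lower, and 10 adjusted over the list alone (camera adjusted p = 2.42e-09, and adjusted p = 0.189 with an estimated correlation). Without the arrays high in other tissues Rag1, Trbv1, Ccr9, Cd3g, Thy1 and Cd3d were at −2.40, −1.92, −1.38, −1.28, −0.997 and −0.98, no longer called on fewer arrays (limma adjusted p = 0.125, 0.151, 0.222, 0.241, 0.0773 and 0.113), and with tissue scores as covariates the list mean was 0.0034 and Gzma had limma adjusted p = 0.392. The calls of Rag1, Cd3g and Cd3d held in 39 of 45, 12 of 45 and 35 of 46 alternatives. Antigen presentation (3 of 13 lower adjusted over the list alone, Tap1 −0.47, H2-K1 −0.30, H2-D1 −0.26), interferon response (2 lower adjusted over the list alone, Irf7 −0.40, Bst2 −0.30, Ifit3 −0.40) and skeletal muscle (Acta1 −1.55, Mylpf −1.56, Atp2a1 −1.05) ranked lower with 0 genes called. Their camera adjusted p was 9.98e-07, 2.94e-04 and 8.77e-04, and adjusted p = 0.277, 0.421 and 0.844 with an estimated correlation. The skeletal muscle mean of −1.06 ran from −1.47 to −0.15 over its alternatives, and KO air P3 replicate 2 held these muscle genes at 5.99. With tissue scores as covariates the antigen presentation mean turned to 0.09 (camera adjusted p = 0.367), and with array weights these 6 antigen presentation and interferon genes were called (limma adjusted p from 6.35e-04 to 0.0462). In the glucocorticoid list Per1 (−1.02 ± 0.23) was called and Fkbp5 (−0.72) and Klf9 (−0.61) were not (camera adjusted p = 0.00273, and adjusted p = 0.710 with an estimated correlation). Without the arrays high in other tissues Per1 stayed at −1.02, with limma adjusted p = 0.105 on fewer arrays.

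By limma 217 genes were called, 124 higher and 93 lower (2494 at an unadjusted p under 0.05), and 18 differed at least 2-fold. After loess 451 were called, with 44.1% higher against 57.1%, with array weights 985, without KO air P2 replicate 2 691, and without the arrays high in other tissues 83.

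**Figure D4:**
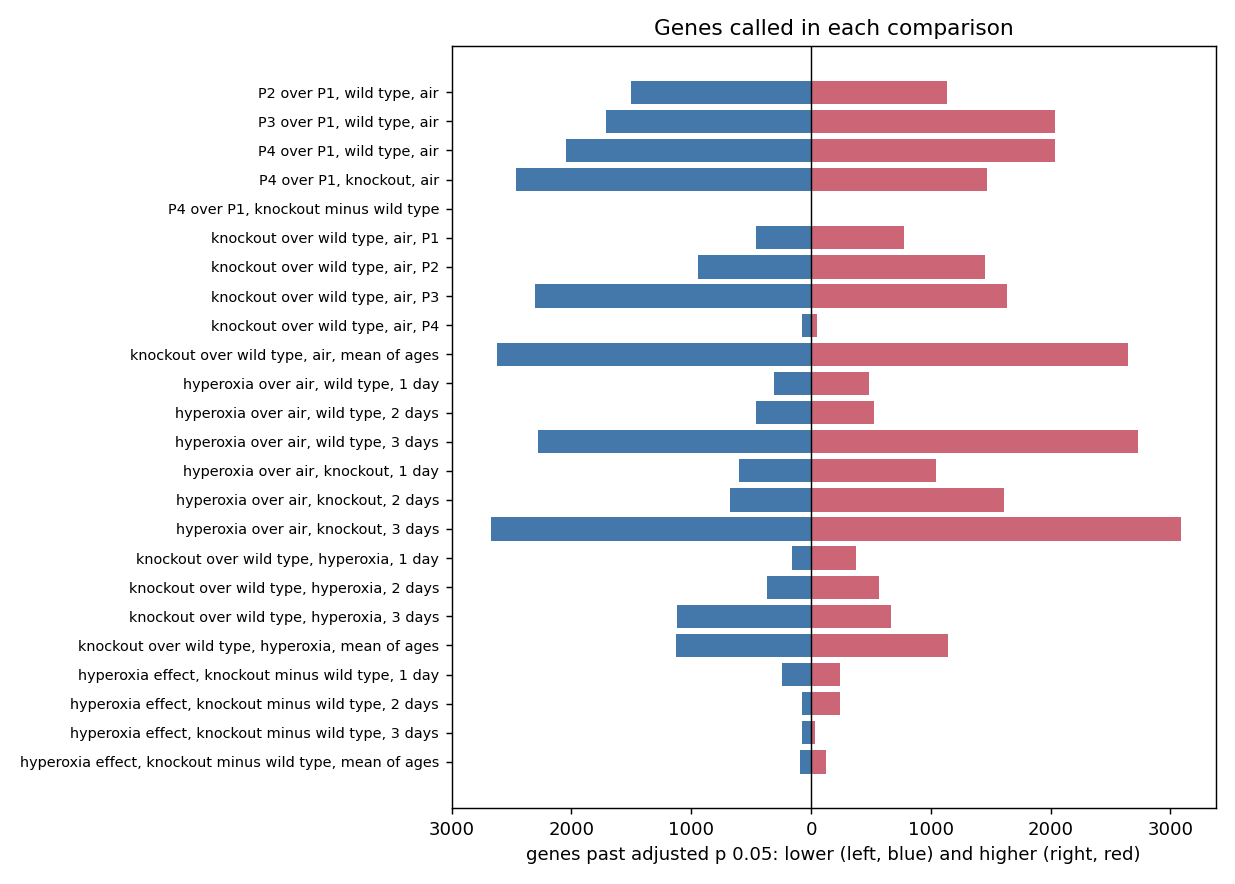
Genes past a limma adjusted p of 0.05 in each of the 24 comparisons, with lower genes to the left of 0 and higher genes to the right. Counts run from 5 for the difference between genotypes in the change from P1 to P4 to 5760 for 3 days of hyperoxia in KO.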

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

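The tests on the first component of liver genes, on a deletion acting alike in every pup, on stretches of another strain and on both neighbours of an array were chosen only after the result was seen, as were the 2 alternatives that use other-tissue scores.

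The results in this part stood out because the genotypes differed in a test of the difference itself, either in the hyperoxia effect or in the change from P1 to P4. The second of these called 5 genes, and 13 of 100 splits of the arrays called as many, with 1507 in the highest other split, so chance cannot be excluded there. For the hyperoxia effect the difference called 489, 320 and 102 genes after 1, 2 and 3 days and 217 for their mean. As many were called by 10, 14, 7 and 3 of 100 splits, with 2128, 4438, 1412 and 396 in the highest other split. For single days chance cannot be excluded. For the mean the share of splits was under 0.05, but a split takes away the genotype effect in air as well. The splits therefore cannot decide about chance for the difference in the hyperoxia effect alone. Splits that call several times the real count point to a structure among the arrays. The splits exchange genotypes within an age and exposure, so that structure includes the genotype effect itself. Other tissues may add to it after 1 day: with their scores as covariates 9 genes were called, and 31 without the arrays high in them, against 336 and 251 after 2 days and 148 and 67 after 3. With the sex-gene score 290, 325 and 45 were called.

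Single arrays moved the daily counts. The 1-day count was 96 without KO air P2 replicate 1, 1658 without KO air P2 replicate 2, 320 without WT air P2 replicate 1, 292 and 147 without WT hyperoxia P2 replicates 1 and 2, and 252 and 195 without KO hyperoxia P2 replicates 1 and 2. The 2-day count was 157 and 152 without WT air P3 replicates 1 and 2, 143 without WT hyperoxia P3 replicate 1, 211 and 191 without KO air P3 replicates 2 and 3, and 168 and 137 without KO hyperoxia P3 replicates 1 and 3. The 3-day count was 47 and 43 without WT air P4 replicates 1 and 3, 36 without WT hyperoxia P4 replicate 3, 54, 159 and 51 without KO air P4 replicates 1, 2 and 3, and 67 and 409 without KO hyperoxia P4 replicates 2 and 3. The mean called 691 without KO air P2 replicate 2.

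Among NRF2 targets the difference was −2.12 for Gpx2, −1.42 for Srxn1, −1.22 for Nqo1, −0.81 for Txnrd1, −0.80 for Gclc, −0.54 for Gclm and −0.42 for Hmox1, with a list mean of −0.51. All but Hmox1 passed in each of their alternatives. Hdc (1.38) passed in 47 of 47 alternatives, with limma adjusted p from 1.39e-07 to 9.96e-05. Slitrk6 (0.95), Il33 (0.72), Ppp1r3c (0.70), Wif1 (0.68), Nr1d2 (0.65) and Per1 (−1.02) passed in 45 of 46, 45, 46, 45, 44 and 46 of 47, with limma adjusted p of at most 0.0849, 0.181, 0.0957, 0.152, 0.156 and 0.105.

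T cell genes also differed: Rag1 (−2.85), Trbv1 (−2.52), Ccr9 (−2.29), Cd3g (−1.96), Thy1 (−1.74), Gzma (−1.67) and Cd3d (−1.58), with limma adjusted p over their alternatives of 0.00175 to 0.125, 4.02e-04 to 0.774, 3.21e-05 to 0.222, 1.55e-04 to 0.241, 1.77e-06 to 0.407, 1.32e-05 to 0.392 and 8.69e-06 to 0.113. The Rag1 call also ended without WT air P3 replicate 1 (0.0530), WT air P4 replicates 1 and 2 (0.0531 and 0.0587), WT hyperoxia P4 replicate 3 (0.0557) and KO air P3 replicate 2 (0.0510). The Cd3d call ended (limma adjusted p from 0.0502 to 0.0599) without any one of WT air P3 replicate 1 and P4 replicate 2, WT hyperoxia P2 replicate 2, P3 replicate 2 and P4 replicate 3, KO air P2 replicate 3, P3 replicate 2 and P4 replicate 3, and KO hyperoxia P2 replicate 2. A candidate source is thymus carried along with 2 lungs of KO air P2, since with the tissue scores as covariates Trbv1 went to −0.27 and Thy1 to −0.36. The thymocyte list was written after lymphocyte genes had been seen to differ, so that covariate is no independent test. Without the arrays high in other tissues Rag1 was still at −2.40. The KO air P2 array that stayed, replicate 2, itself held thymocyte genes at 1.28, so that omission does not decide it either.

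Further lists whose mean differed were lymphocytes (−0.80), skeletal muscle (−1.06), glucocorticoid response (−0.35), antigen presentation (−0.34), AhR targets (−0.33), interferon response (−0.22), cytokines and acute inflammation (−0.20), mitosis (−0.20), lung development signals (0.15) and DNA replication (0.15). With tissue scores as covariates mitosis turned to 0.30 (camera adjusted p = 0.00363), antigen presentation to 0.09 (0.367) and lymphocytes to 0.0034 (0.738). Over their alternatives skeletal muscle ran from −1.47 to −0.15 and DNA replication from 0.04 to 0.58. Mitosis passed in 37 of its 46 alternatives, DNA replication in 38, cytokines in 29 and antigen presentation in 44, with adjusted p of at most 0.844, 0.844, 0.844 and 0.367. With an estimated correlation their camera adjusted p ran from 0.0541 to 0.844, and that of the NRF2 list was 4.95e-06.

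Liver transcripts differed by genotype. A score more than 1 log2 unit above the KO median was found in 12 of 21 WT and 1 of 21 KO arrays (Fisher exact p = 5.0e-04), and Alb reached 14.87 in WT air P2 replicate 2. That test takes arrays as independent, which carry-over between arrays, left open below, would break, so its p may be too small. In WT air, replicates 2 and 3 scored 5.11 and 1.69 at P1, 7.49 and 3.11 at P2, and 5.32 and 2.67 at P3, relative to the median of all arrays. WT hyperoxia P4, at 4.46, 1.20 and 3.01, shows no such order. A deletion acting alike in every pup would need a score above that limit in at least 19 of 21 WT arrays, and 9 lay within 1 unit, which argues against that explanation. Liver tissue carried along with single lungs may be the source: 11 of 11 liver genes outside the list (100%) rose and fell with it within groups (r from 0.627 to 0.994), though the list's first component held 95.8% of its deviation against at most 97.6% in 1000 random lists, so that test decides nothing. Why mostly WT pups carry it stays open, such as dissection by litter or a developmental difference, neither tested.

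The 5271 genes that differed by genotype in air were checked for alleles linked to the deleted locus. Of 200 neighbours of Nfe2l2 32.0% were called, against 28.9% of other genes (odds ratio 1.16, 95% 0.843 to 1.57, Fisher exact p = 0.347). By this loose call no clear excess was seen among the neighbours, but 200 genes could never be the whole cause of 5271 calls. The narrower set of genes called the same way at all 7 ages and exposures reads otherwise. Of it, Rbm45, Dnajc10 and Nckap1 lie among the 200 neighbours. Only 39 others, Nfe2l2 aside, lie among the rest of the 18146 genes placed on chromosomes. That is a larger share near the locus, seen afterwards and not tested. A short stretch could also go unseen among the 200 neighbours, so linked alleles are not excluded. Sex of the pups is argued against as the whole cause, since 5287 genes were called with the sex-gene score. Linked alleles stay open for Rbm45, Dnajc10 and Nckap1, at 8, 25 and 28 genes from Nfe2l2 and called at all 7 ages and exposures, the last 2 named after their values were seen. They stay open for other called neighbours too, such as Itga6 at −30 genes, with 0.86 in air and 1.47 in hyperoxia. Stretches of another strain may explain a part: of the genes called the same way at all 7 ages and exposures, 39 remain without Nfe2l2 and these neighbours, and 15 of them lay within 20 genes of another one, against a median of 2 and at most 14 in 10000 random sets (permutation p = 1e-04, the smallest they can give). They are Trim68, Trim34a, Trim5, Trim12c, Rrp8 and Tpp1 on chromosome 7, H2-K1, Pfdn6, Mad2l1bp and Klc4 on 17, Plcb1, Jag1 and Macrod2 on 2, the chromosome of Nfe2l2, and Aox1 and Aox3 on 1. Shared probes of Trim paralogs, or direct control of Aox1 by NRF2, stay open and were not tested.

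Transcripts of the other sex appeared in single arrays. Where the array numbered before in its group was of the other sex the excess averaged 0.947 (n = 16), against 0.172 (n = 12) elsewhere, a difference of 0.77 (95% 0.434 to 1.13, permutation p = 6.6e-04). Carry-over from the array numbered before may be the source, and mixing in no order is argued against, since the following array gave −0.17 (95% −0.556 to 0.238, permutation p = 0.458). Exceptions were WT hyperoxia P2 replicate 2 and KO hyperoxia P4 replicate 1, with 0.859 and 0.662 and no such neighbour, and KO hyperoxia P3 replicate 3, with 0.053 despite one. That the numbers follow the order of handling is assumed, and tissue pooled or mixed before extraction stays open and was not tested.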

How the results depend on the processing

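The covariates and omissions based on other-tissue scores were chosen after the data were seen, the rest before. Over all alternatives the named genes were the same in direction and side of the threshold 4881 times, lost the call 168 times, gained it 59 times, turned sign 64 times from a value that was not called, and 0 times from a called one. Of those 64, Nfe2l2 from P1 to P4 in WT was itself called, at −1.46 with the mean of its probe sets and −3.21 in the second one. That second probe set read alike in WT and KO, so neither call can be read as a fall of the deleted transcript. The lists gave 2379, 256 lost and 6 reversed. With a correlation estimated per list 22 of 117 lists passed, and 95 did not. The trend with robust variances, and the upper 60 percent of genes by mean level, moved no count by more than 1.5 times. The cause of the moved counts was not tested. A fit on only the arrays of a contrast has fewer degrees of freedom, equally so in every comparison of 3 arrays with 3. Yet it called 3758 genes against 4083 for P4 over P1 in WT. For the genotype in air it called 195 against 132 at P4, but 9 against 2391 at P2. Fewer degrees of freedom alone therefore do not account for the losses. Arrays of WT air P2 had a mean r with their own group of only 0.978 to 0.986, and whether that spread matters was not tested. The covariate alternative was not read for 5 lists and 16 genes that enter the scores. Where leaving arrays aside left KO air P2 with 1 array, limma assumes that it varies like the other groups. Signal over background limits genes near the floor: the arrays' 10th percentile had a median of 4.27, so a fall below it cannot be measured.

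With array weights the P3 and P4 changes in WT called 6254 and 6381 genes and their difference by genotype at P4 1054. The genotype in air called 4454, 6447 and 944 at P1, P3 and P4. Hyperoxia called 1232 and 3739 in WT and 3048 and 4391 in KO after 1 and 2 days. The genotype in hyperoxia called 2459 and 3820 after 1 and 2 days and 4530 for the mean. The difference in the hyperoxia effect called 1383, 2084 and 788 by day and 985 for the mean.

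With cyclic loess the difference at P4 called 41, the genotype in air at P4 269, and the difference in the hyperoxia effect 199 after 3 days and 451 for the mean. For 2 days 54.7% of those genes were higher, against 75.9%. With every probe set on its own, which tests more features, the difference at P4 called 34, the genotype in air 1944, 4085 and 219 at P1, P2 and P4, the genotype in hyperoxia 972, 1753, 2927 and 4037 by day and for the mean, and the difference in the hyperoxia effect 180 after 3 days. With the mean of all probe sets the difference at P4 called 3 and that in the hyperoxia effect 172 after 2 days.

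A fit on only the arrays of the contrast called 860 for WT at P2, 272 and 9 for the genotype in air at P1 and P2, 12 and 483 for hyperoxia in WT after 1 and 2 days, 4 in KO after 1 day, 284 for the genotype in hyperoxia after 3 days, and 5 and 48 for the difference in the hyperoxia effect after 1 and 3 days. The sex-gene score gave 519 for hyperoxia in WT after 1 day, and 290 and 45 for the difference after 1 and 3 days.

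With other-tissue scores as covariates the difference at P4 called 25, the genotype in air 173 at P2 and 2884 for the mean, hyperoxia in KO 12 after 1 day, and the difference in its effect 9 after 1 day. There 6 list means reversed: mitosis in the difference at P4 (−0.0051) and in the mean hyperoxia difference (0.3043), DNA replication by genotype in air at P4 (−0.2451), antigen presentation by genotype in air (−0.0094) and in the hyperoxia difference (0.0883), and lymphocytes in the latter (0.0034). Leaving aside the arrays with other-tissue scores over 4, the difference at P4 called 2, the genotype in air 472 and 75 at P2 and P4, hyperoxia in KO 149 after 1 day, and the difference in its effect 31 and 67 after 1 and 3 days and 83 for the mean.

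Leaving out 1 array at a time gave 1 to 42 for the difference at P4, 673 to 1442, 1210 to 3161 and 61 to 129 for the genotype in air at P1, P2 and P4, 231 to 1069 and 458 to 792 for hyperoxia in WT after 1 and 2 days, 707 to 3125 and 1356 to 1899 in KO, 186 to 516, 357 to 645 and 932 to 1888 for the genotype in hyperoxia by day, and 96 to 1658, 137 to 318, 36 to 409 and 152 to 691 for the difference in the hyperoxia effect by day and for the mean. The other 9 counts stayed within 1.5 times.

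The numbers of the replicates share only a number between groups: 14 of 42 arrays resembled their own number most. With the replicate block the 5 leading counts were 4141, 5278, 5083, 2343 and 230.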

Other observations

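The tests in this part that concern splits of the arrays were chosen before the results were seen, and the lists below were picked from their results.

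Beside p53 and NRF2 targets, hyperoxia raised genes of the ATF4 stress response, which cells switch on when protein synthesis is strained or amino acids are short. The list score, a level and not a change from air, was −0.03 ± 0.06, 0.26 ± 0.05 and 0.55 ± 0.09 in WT after 1, 2 and 3 days, and in KO −0.12 ± 0.04, 0.26 ± 0.05 and 0.45 ± 0.14 (SD, n = 3). In air at P2 to P4 single arrays lay at −0.26 to −0.09 in WT and −0.39 to −0.08 in KO. After 2 days 8 of 20 genes were higher and 1 lower in WT, and 12 higher in KO. With an estimated correlation camera gave adjusted p = 0.0245 and 0.0159. After 3 days 11 were higher and 4 lower in WT, and 10 higher and 2 lower in KO (camera adjusted p = 2.84e-05 and 2.58e-05, and adjusted p = 0.0964 and 0.113 with an estimated correlation). After 1 day the list did not pass camera. For targets of the aryl hydrocarbon receptor (AhR), 8 genes, the score was 0.35 ± 0.11 in WT and 0.12 in KO after 2 days, and 0.13 ± 0.08 and −0.36 ± 0.14 after 3. At P3 in air it lay at −0.35 to −0.17 in WT and −0.33 to −0.22 in KO. At P4 in air it lay at −0.02 to 0.14 in WT and −0.25 to −0.23 in KO. For AhR targets camera adjusted p with an estimated correlation was 0.0245 for hyperoxia in WT after 2 days and 0.0541 for the difference between genotypes.

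The circadian clock list stood at 0.41 ± 0.10 in WT and −0.03 ± 0.06 in KO (SD, n = 3) at P1 in air, and at −0.23 ± 0.02 and −0.28 ± 0.09 at P4. At P1 6 of 16 genes were lower in KO (camera adjusted p = 4.24e-08, and adjusted p = 0.00407 with an estimated correlation). Per1, which glucocorticoids also induce, was higher in KO at P2 and P3 by 1.77 and 2.31. The hour at which each pup was taken is not given in the sources used here, and no explanation was tested. After 3 days of hyperoxia 7 of 12 club cell markers were lower in each genotype (camera adjusted p = 0.00378 in WT and 2.84e-04 in KO, and adjusted p = 0.456 and 0.374 with an estimated correlation). Their mean was −0.72 ± 0.54 in WT and −1.07 ± 1.02 (SD, n = 3) in KO, and was already at −0.74 ± 0.14 in KO air at P4.

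For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05, and in each the real split alone, 1 of the 10, reached its count. Real and highest other counts were 2638 and 76, 3749 and 2, and 4083 and 1 for WT at P2, P3 and P4 against P1, and 3932 and 93 for KO at P4. For the genotype in air they were 1233 and 25, 2391 and 1457, 3939 and 1, and 132 and 1 from P1 to P4. For hyperoxia in WT they were 788 and 11, 982 and 0, and 5010 and 0 by day, and in KO 1648 and 772, 2288 and 1, and 5760 and 110. For the genotype in hyperoxia they were 538 and 2, 934 and 0, and 1786 and 116. For the mean difference by genotype they were 5271 and 3550 in air and 2270 and 836 in hyperoxia. In each 1 of 100 splits reached the count, the real one. That share is under 0.05, which makes chance unlikely but does not exclude it. The splits also treat pups as independent of one another, while dissection by litter and carry-over between arrays stay open.

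Y-linked transcripts were present in 1, 1, 1 and 2 of 3 arrays of WT in air from P1 to P4, in 2, 1, 2 and 0 of KO in air, in 3, 2 and 1 of WT in hyperoxia by day, and in 1, 2 and 3 of KO in hyperoxia. KO air P4 replicate 2 deviated most from the common distribution of values, by at most 0.199 log2 units, against 0.126 in the next array.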
